A study of Mus musculus with 51 samples.

How the data were processed

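Gene expression was measured in alveolar macrophages, the resident phagocytes of the airspaces, collected from mouse lungs after an in vivo exposure. Per the labels, RNA was extracted with RNeasy columns, labelled with biotin by the Affymetrix two-cycle procedure from 100 ng of total RNA, and hybridized to Affymetrix mouse expression arrays. The 51 arrays formed 15 groups by genotype, time and exposure, 30 from C57Bl/6 mice (WT) and 21 from gp91phox-/- mice (KO). The labels name the replicates of a group as biological replicates and do not state how many mice stood behind an array. The p-values therefore refer to the spread between the arrays as labelled, pooled over all groups.

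The values deposited by the authors were signal intensity on a linear scale, 1 value per probe set and array. The labels name GCOS and RMA as the authors' tools, with no version and no role. The values fit the signal that GCOS computes and scales per array: the mean of every array after trimming 2% at each end was about 500, and the arrays did not share a distribution, which RMA with its usual quantile normalization would give. Arrays carry no read depth, and their number limits the precision. The genome build behind the probe sets was not stated, so no coordinates are given, and the RefSeq annotation of assembly GRCm38.p6 served only for names and for which genes neighbour each other.

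Of 22690 probe sets, 64 hybridization and labelling controls were left out and 22626 were tested. The annotation table of the platform gave 20380 of them exactly 1 gene symbol, 691 several symbols and 1555 none. A gene was represented by the probe set with the highest mean over the 51 arrays among those with 1 symbol, which gave 12393 genes. Values were taken to log2 with no pseudocount, no filter and no further normalization. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes at their default settings), with 1 mean per group and all 51 arrays in the fit. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets within a comparison, and a probe set was called at an adjusted p under 0.05. All tests of differences were two-sided. An error after ± is the standard error of the log2 difference from limma, or the SD between arrays where so stated. The limma error and p-value use 1 spread per probe set, pooled over the 15 groups. For a group whose arrays varied more than this, both understate the uncertainty.

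The 25 comparisons were each conidia dose against mock instillation per genotype and time, dose against dose, the response at 4 h against that at 2 h, the difference between the genotypes in each response, KO against WT as a mean over the 7 conditions both had and in untreated mice, mock against untreated, and beads against mock and against conidia. The comparisons, the rule for naming genes, the gene lists and most of the other settings were fixed before the data were examined. In each comparison the genes that may be named were the 12 largest rises and the 12 largest falls among called genes, members of the gene lists, and Cybb, the gene disrupted in the KO mice. A gene outside this rule is named with the statement that it was chosen after its values were seen.

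The 26 lists, written from general knowledge, covered cytokines, chemokines, the NF-kB pathway and its feedback, interferon-responsive genes, fungal recognition and phagocytic receptors, the NADPH oxidase, antioxidant and NRF2 targets, immediate-early transcription factors, heat shock and unfolded protein, glycolysis and hypoxia, lysosome and phagosome, cholesterol synthesis and export, cell cycle, apoptosis regulators, proteases and matrix, alternative activation and antimicrobial effectors. They also covered markers of alveolar macrophages, neutrophils, monocytes and dendritic cells, T and NK cells, B cells, lung epithelium, endothelium and stroma, and erythroid cells, and sex-linked genes. Lists were counted by called members, with p-values adjusted over all probe sets and adjusted over the list alone, and tested against the other genes with camera from limma at a preset correlation of 0.01, adjusted over the 26 lists. Of 650 list tests, 94 were called with the preset correlation, and 10 of these held with a correlation estimated from the data. Each of the 10 is named in the Results.

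The fits were tested on simulated data in which 200 probe sets were changed among 22626. With 4 arrays against 4 as in WT at 4 h with e7 conidia, 31% of 2-fold and 68% of 4-fold changes were called, and 64.6% and 98% among probe sets in the upper part by mean signal. With 3 against 3 as in KO at 2 h with e7 conidia, 34% and 59% were called, and with 2 against 4 as in beads against mock, 23% and 48%. No called change had the wrong direction, and of 22426 unchanged probe sets 2, 3 and 0 were called. These counts give no false-call rate for real arrays that lie apart. A chemokine list shifted by 1 on the log2 scale was called by camera, and so was 1 of 25 unshifted lists, the erythroid markers. The lists called depend on the random draw of the simulated data.

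Other settings chosen in advance left out the dimmer part of the probe sets by mean signal, kept 1 probe set per gene, fitted only the groups of a comparison, used a trend and robust moderation, weighted arrays by quality, treated replicate number as a block, quantile normalized the values, added the log2 ratio of 3' to 5' control probe sets as a covariate, took the WT 2 h mock group as reference for the WT 4 h groups, and left out each array in turn. Settings chosen after seeing the data set signals under 50 to 50 before log2, and left out WT 4 h arrays with high neutrophil markers, or WT e7 arrays that lay apart. Comparisons between groups of at least 3 arrays were repeated on other splits of the same arrays, all splits where there were at most 100 and 100 drawn splits otherwise. For differences between responses the mean response was first subtracted from the conidia arrays, a step added after first counts. Figures were drawn with matplotlib 3.10.9. None of the deposited arrays was left out of the comparisons reported.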

Results

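The transcriptome of alveolar macrophages was measured after conidia, the airborne spores of the mould Aspergillus fumigatus, or polystyrene beads had been instilled into the lungs of living mice. Mice were either C57Bl/6 (WT) or gp91phox-/- (KO), which lack the membrane subunit of the phagocyte NADPH oxidase, the enzyme that makes the oxidative burst. The stated purpose was to learn whether macrophages of a normal and of an immune-compromised host answer differently, and whether this bears on the susceptibility to invasive aspergillosis. WT groups held 4 arrays each for untreated mice at 0 h and for mock, e6 conidia and e7 conidia at 2 h and at 4 h, and 2 arrays for beads at 4 h. KO groups held 3 arrays each for the same conditions except beads. The labels give the doses as e6 and e7, which differ by a factor of 10, and give no number of beads. The treatment field of the WT 4 h mock arrays names conidia while their titles name mock, and the titles were followed. Pairs of arrays of the same group correlated between 0.8993 and 0.9491 over probe sets. The log2 ratio of 3' to 5' control signals, a measure of RNA length, lay between 2.09 and 4.85 on the WT 2 h e7 arrays and between 0.93 and 1.47 on their mock arrays, without overlap (difference 1.91, exact permutation p = 0.0286). WT mock at 2 h also lay apart from untreated (difference -1.58, exact p = 0.0286), and the bead arrays, at 4.11 and 5.32, lay apart from their mock arrays at 1.19 to 2.34 (difference 3.11, exact p = 0.0667). These p-values are the smallest that groups of such sizes can give, and the smallest for 3 arrays against 3 is 0.1. After adjustment over the comparisons the lowest was 0.229, which does not show that the groups were alike.

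Cybb encodes gp91phox, and its signal was read first in every array as a check of genotype. On the log2 scale it lay between 10.59 and 12.12 on the 30 WT arrays and between 6.77 and 9.06 on the 21 KO arrays, with no overlap. As a mean over the 7 conditions both genotypes had, Cybb was 6.71-fold lower in KO (log2 difference -2.75 ± 0.11, adjusted p = 9.66e-22). In untreated mice the difference was -2.52 ± 0.29 (adjusted p = 3.36e-07; 3 KO and 4 WT arrays). Conidia did not move Cybb in WT at 4 h past the threshold (0.25 ± 0.27, adjusted p = 0.627).

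**Figure D1:**
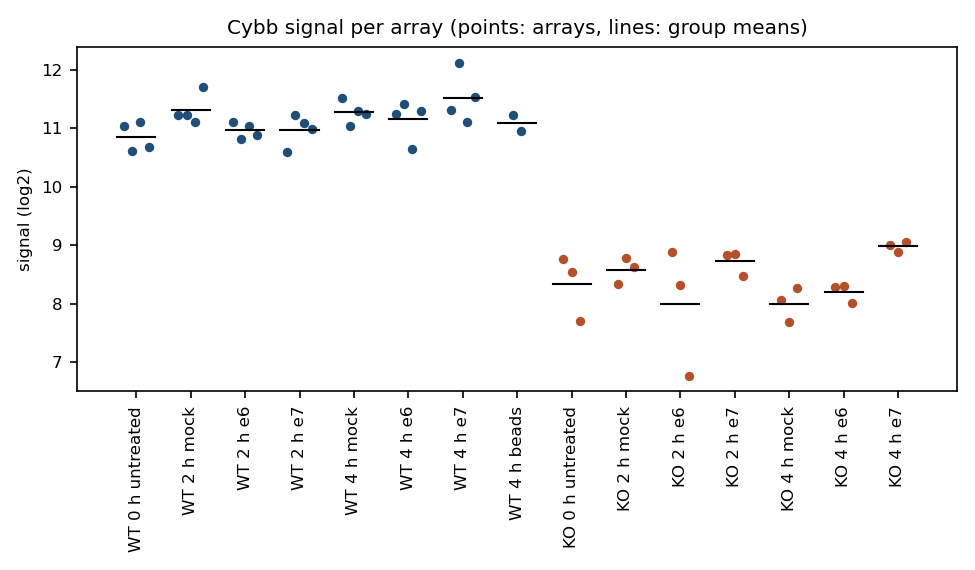
Log2 signal of Cybb (vertical axis) on every array by group, with points for single arrays and lines for group means. The 30 WT arrays lie between 10.59 and 12.12 and the 21 KO arrays between 6.77 and 9.06.

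The first question was what normal macrophages do within 2 h of meeting conidia. With e7 conidia, WT macrophages raised Cxcl2 and Cxcl1, which encode chemokines that attract neutrophils. Cxcl2 rose by 4.12 ± 0.69 on the log2 scale (adjusted p = 0.00135), from 7.97 ± 0.24 in mock to 12.09 ± 0.54 with conidia (SD, n = 4 each), and Cxcl1 rose by 2.89 ± 0.5 (adjusted p = 0.00226). Rgs1, an inhibitor of G-protein signalling downstream of chemokine receptors, rose by 2.61 ± 0.31 (adjusted p = 7.1e-06). The immediate-early transcription factors Egr1 and Atf3 rose by 2.6 ± 0.49 and 1.39 ± 0.26 (both adjusted p = 0.00479), and Nfe2l2, which encodes the antioxidant regulator NRF2, by 0.58 ± 0.11 (adjusted p = 0.00555). For each of these genes the 4 conidia arrays lay above the 4 mock arrays. Ccl3, another chemokine, rose by 2.58 ± 0.63 (adjusted p = 0.0271), and Tlr4, a receptor for microbial products, by 0.77 ± 0.18 (adjusted p = 0.021). Among falls were Batf3, a transcription factor (-1.53 ± 0.32, adjusted p = 0.00896), and Cd9, a surface protein abundant on alveolar macrophages (-0.8 ± 0.17, adjusted p = 0.00954). Tnf, which encodes the cytokine TNF, did not pass (0.94 ± 0.35, adjusted p = 0.161).

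In all, 365 probe sets were called in WT at 2 h with e7 conidia, 191 higher and 174 lower, from 218 genes. The count was 45 with the 3'/5' covariate, which ended the calls of Egr1, Tlr4, Batf3 and Cd9, and 4 in a fit of only the 8 arrays, which ended those of Cxcl1, Atf3, Nfe2l2, Ccl3, Tlr4, Batf3 and Cd9. Of the 18 alternatives run, Cxcl2 and Rgs1 passed under each. Ccl3 was lost under 9 of them, without e7 replicates 1, 2 or 4 or any mock array among others, and Tlr4 under 8, without e7 replicates 1, 2 or 4 or mock replicates 2 or 3. Cd9 was lost under 7, without e7 replicate 1, mock replicates 2 or 3 or with quantile normalization, and Batf3 under 4, without mock replicate 2. The count depended on single arrays: it was 63, 91, 173 and 591 without mock replicates 2, 3, 1 and 4, and 92, 152 and 177 without e7 replicates 1, 4 and 2. Of 24 measured immediate-early factors 3 were higher (7 when adjusted over the list alone; camera adjusted p = 0.000148, adjusted p = 0.22 with an estimated correlation). Of 25 chemokines 3 were higher (3 adjusted over the list alone), and of 15 alveolar macrophage markers 2 were lower (5 adjusted over the list alone; camera adjusted p = 0.0179, adjusted p = 0.22 with an estimated correlation). With e6 conidia at 2 h, limma called 0 probe sets (945 at an unadjusted p under 0.05), and 1 without e6 replicate 4. Cxcl2 (1.98 ± 0.69), Ccl3 (1.7 ± 0.63) and Egr1 (1.32 ± 0.49) lay higher than in mock without passing (adjusted p = 1 for each). Camera called the immediate-early list upward (adjusted p = 0.00569, adjusted p = 0.461 with an estimated correlation), with 0 members called, also 0 adjusted over the list alone.

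By 4 h, WT macrophages given e7 conidia had raised some cytokine, chemokine and antioxidant genes. Genes of the oxidase and of the replication machinery were lower, but those named below lost their calls without e7 replicates 2 and 3. Cxcl1 rose by 4.48 ± 0.5 (adjusted p = 4.09e-07), from 6.02 ± 1.85 to 10.5 ± 0.21 (SD, n = 4 each), and Tnf by 2.78 ± 0.35 (adjusted p = 3.57e-06), from 7.06 ± 0.74 to 9.84 ± 0.59. Hmox1, which encodes the stress-induced haem oxygenase 1, rose by 1.66 ± 0.3 (adjusted p = 0.00036), and Maff, a small Maf transcription factor, by 2.06 ± 0.21 (adjusted p = 5.54e-08). Plk2, a stress-induced kinase, rose by 4.21 ± 0.66 (adjusted p = 9.05e-05) and Il1a, which encodes interleukin 1 alpha, by 1.69 ± 0.34 (adjusted p = 0.000928). For these 6 genes the 4 conidia arrays lay above the 4 mock arrays. Cxcl2 rose by 3.95 ± 0.69 (adjusted p = 0.000204), but only 1 conidia array lay above all mock arrays, because mock replicate 3 lay at 13.86 and the other mock arrays between 7.78 and 8.71 (SD of mock 2.87). Without that array the rise was 5.37. Egr1 (3.27 ± 0.49), Clec4e, which encodes the fungal receptor Mincle (1.46 ± 0.4), and Irf1 (0.86 ± 0.13) also rose, with 3, 0 and 4 of 4 conidia arrays above all mock arrays. Over the alternatives Clec4e ranged from 1.18 to 2.73. Lower were Ncf4, the p40 subunit of the NADPH oxidase (-1.12 ± 0.22, adjusted p = 0.000694), and Cyba, the partner of gp91phox in the membrane (-0.98 ± 0.24, adjusted p = 0.00432), the latter with 3 of 4 conidia arrays below all mock arrays. Mcm2, a replication helicase subunit, fell by 1.39 ± 0.31 on the log2 scale, and Siglecf, a lectin that marks alveolar macrophages, by 0.67 ± 0.13.

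This comparison, WT at 4 h with e7 conidia against mock, called 3512 probe sets, 1321 higher and 2191 lower, from 2172 genes. A fit of only the 8 arrays, with their own spread, called 0 probe sets. Single arrays of the e7 group moved the count: it was 1622 without replicate 3, 1964 without replicate 2 and 5305 without replicate 4. E7 replicates 2 and 3 lay at 68.3 and 96.5 on the leading principal component, against 28.7 and 0.5 for replicates 1 and 4, and the count was 204 without both. It was 1165 without the 3 WT 4 h arrays with high neutrophil markers, among them e7 replicate 3 (7.37, as mean log2 signal) and mock replicate 3 (8.7). Both removals were chosen after seeing the data. The falls of Cyba (-0.17) and Ncf4 (-0.54), and that of Mcm2 (-0.84), were smallest and did not pass without e7 replicates 2 and 3, and Il1a lost its call there. Cyba was also lost without e7 replicate 3 (-0.57) and without the 3 arrays with high neutrophil markers (-0.54). Clec4e was lost without e7 replicate 3, without mock replicates 1 or 4, and without e7 replicates 2 and 3. Immediate-early factors had 9 higher and 1 lower of 24, the same adjusted over the list alone (camera adjusted p = 0.000374, adjusted p = 0.334 with an estimated correlation). Antioxidant targets had 6 higher and 1 lower of 20 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00817, adjusted p = 0.129 with an estimated correlation). Cell cycle genes had 7 lower of 29 (8 adjusted over the list alone; camera adjusted p = 0.043, adjusted p = 0.732 with an estimated correlation), and the NADPH oxidase had 1 higher and 3 lower of 10 (1 and 4 adjusted over the list alone; camera adjusted p = 0.0823). Camera did not call cytokines (3 higher and 2 lower of 21, the same adjusted over the list alone, and 3 and 0 with quantile normalization, adjusted p = 0.396) or chemokines (4 and 1 of 25, 5 and 2 adjusted over the list alone, adjusted p = 0.0823). Nor did it call fungal recognition genes (1 and 4 of 29, 2 and 4 adjusted over the list alone, adjusted p = 0.88) or interferon-responsive genes (1 and 4 of 25, the same adjusted over the list alone, adjusted p = 0.855), in which Clec4e and Irf1 were the members called higher.

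With the lower dose at 4 h, Tnf and Ereg were the genes called in WT. Tnf rose by 2.34 ± 0.35 (adjusted p = 0.00116), from 7.06 ± 0.74 to 9.4 ± 0.27, and Ereg, which encodes the growth factor epiregulin, by 2.24 ± 0.34 (adjusted p = 0.00116), from 5.78 ± 0.4 to 8.02 ± 0.46 (SD, n = 4 each). Both were above every mock array on the 4 e6 arrays. They were the 2 probe sets called in this comparison, and neither passed in a fit of only these 8 arrays. The count was 33 without mock replicate 3 and 4 without e6 replicate 2. Chemokines as a list lay higher (camera adjusted p = 3.73e-07, adjusted p = 0.00341 with an estimated correlation), with 0 members called and 5 adjusted over the list alone. So did the NF-kB pathway (camera adjusted p = 3.34e-10, adjusted p = 0.00618 with an estimated correlation; 0 called, 4 adjusted over the list alone). Cell cycle genes lay lower (camera adjusted p = 3.55e-13, adjusted p = 0.0912 with an estimated correlation; 0 called, 1 adjusted over the list alone).

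**Figure D2:**
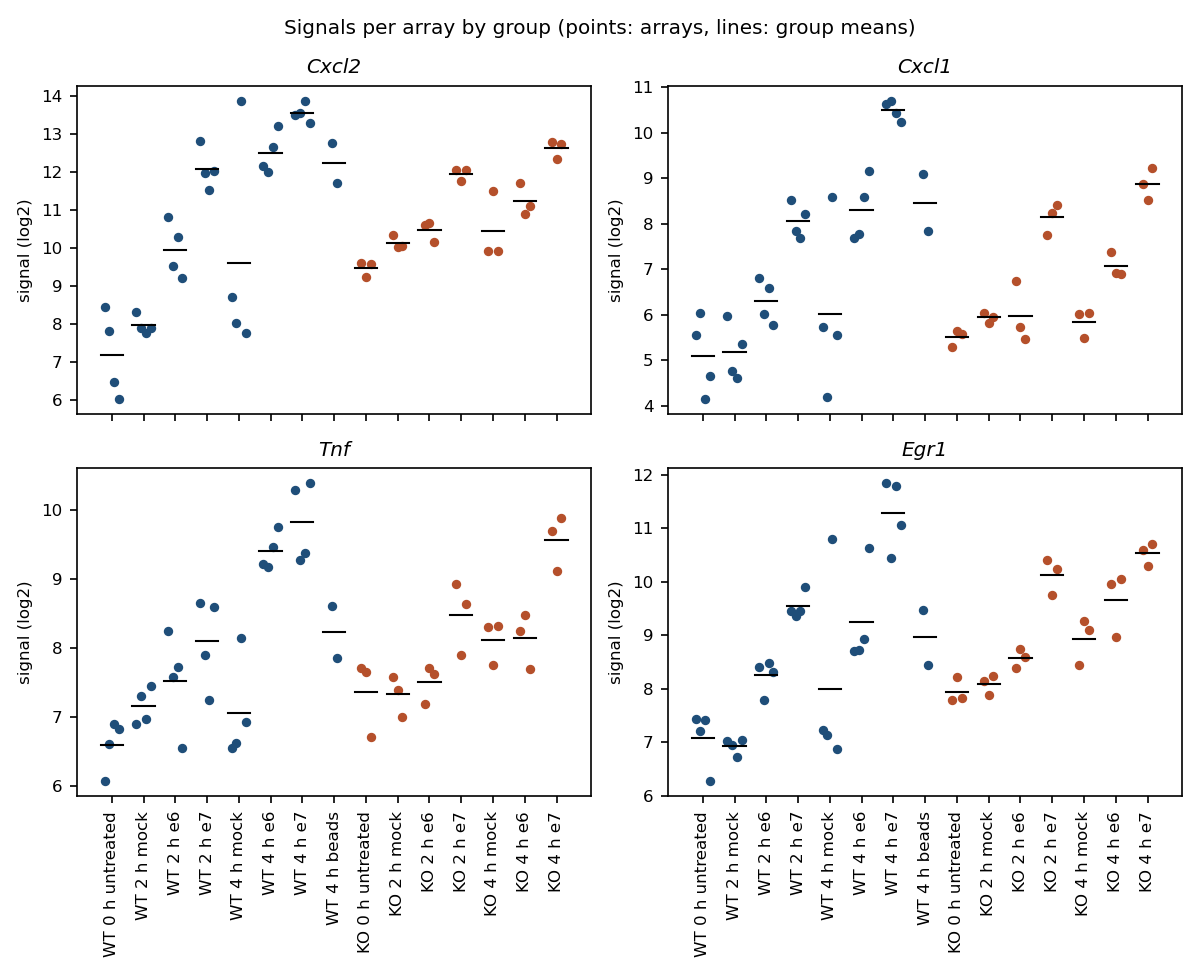
Log2 signal (vertical axis) of Cxcl2, Cxcl1, Tnf and Egr1 on every array by group, with points for arrays and lines for group means. In WT, Cxcl2 rose from 7.97 in mock to 12.09 with e7 conidia at 2 h, and in KO it lay at 10.15 and 11.96.

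The same exposures in KO mice asked how macrophages without the oxidase respond. At 2 h with e7 conidia, KO macrophages raised Cxcl1 by 2.19 ± 0.58 (adjusted p = 0.018), from 5.95 ± 0.12 to 8.14 ± 0.34 (SD, n = 3 each), and Egr1 by 2.05 ± 0.57 (adjusted p = 0.0219). Nlrp3, which encodes an inflammasome sensor, rose by 1.02 ± 0.33 (adjusted p = 0.0438). Casp1, the protease that the inflammasome activates, fell by 0.59 ± 0.13 on the log2 scale (adjusted p = 0.00436). Lat, an adaptor of T cell receptor signalling, fell by 2.52 ± 0.36 (adjusted p = 6.04e-05). For these 5 genes the 3 conidia arrays lay beyond the 3 mock arrays. Cxcl2 (1.81 ± 0.79, adjusted p = 0.14) and Tnf (1.16 ± 0.41, adjusted p = 0.0646) did not pass, but came to pass in 1 and 4 of 15 alternatives, Cxcl2 in a fit of only these groups and Tnf with array weights among others. Several of the largest changes were in genes near the low end of the signals, such as Mcf2, a nucleotide exchange factor (5.43 ± 1.01, from 0.18 in mock, adjusted p = 0.00118), and Il2, which encodes interleukin 2 (4.89 ± 1.19, from 0.83, adjusted p = 0.0104). With signals under 50 set to 50, an alternative chosen after seeing the data, these differences were 0.05 for Mcf2, which no longer passed, and 0.13 for Il2.

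KO at 2 h with e7 conidia called 1957 probe sets, 1382 higher and 575 lower, from 1058 genes. With quantile normalization the split was 650 higher and 927 lower, and the median over all genes moved by 0.21 on the log2 scale between the scalings. In 390 of the calls, 19.9%, both group means were under a signal of 50. Without each array in turn the count was 760, 1274 and 688 for e7 replicates 1, 2 and 3, and 1183, 986 and 782 for mock replicates 1, 2 and 3. Nlrp3 lost its call without any single array, with quantile normalization and with the 3'/5' covariate. Egr1 lost it without e7 replicates 1 or 3 or any mock array, Cxcl1 without e7 replicate 3 or mock replicates 2 or 3, and Casp1 in a fit of only these groups. Lat passed under each of the 14 alternatives run, with a difference of -0.81 under the floor of 50. Immediate-early factors had 3 higher of 24 (6 adjusted over the list alone) and chemokines 2 higher of 25 (2 adjusted over the list alone). T and NK cell markers, the list that holds Lat, had 2 higher, Cd4 and Cd8a, and 1 lower of 17 (the same adjusted over the list alone; camera adjusted p = 0.907), with a median of 0.75 that was -0.12 with quantile normalization. Alveolar macrophage markers lay lower (1 lower of 15, also 1 adjusted over the list alone; camera adjusted p = 0.000712, adjusted p = 0.241 with an estimated correlation). With e6 conidia at 2 h, limma called 0 probe sets in KO (865 at an unadjusted p under 0.05), 2 without e6 replicate 2, 2 without mock replicate 1 and 1 without mock replicate 2. Cxcl2 differed by 0.33 ± 0.79 and Ccl3 by -0.05 ± 0.73 (adjusted p = 1 for both).

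At 4 h few KO genes passed. With e7 conidia, Cxcl1 lay 3.03 ± 0.58 higher than in mock (8.88 ± 0.35 against 5.85 ± 0.31; SD, n = 3 each), above every mock array and short of the threshold (adjusted p = 0.0837). It passed in 6 of 15 alternatives, among them quantile normalization, array weights and the floor of 50 (adjusted p = 0.000627). Cxcl2 (2.18 ± 0.79, adjusted p = 0.512) and Tnf (1.44 ± 0.41, adjusted p = 0.283) did not pass either. The single call was Man2c1os, an antisense transcript of a mannosidase gene near the low end of the signals (-3.42 ± 0.54, adjusted p = 0.00477). With signals under 50 set to 50 its difference was 0 and the call was lost, as it was without e7 replicate 2 and in a fit of only these groups. In this comparison limma gave 1587 probe sets at an unadjusted p under 0.05. The count of 1 became 5 and 3 without e7 replicates 1 and 3, and 8, 13 and 12 without mock replicates 1, 2 and 3. Camera called the immediate-early list upward (adjusted p = 1.15e-05, adjusted p = 0.368 with an estimated correlation; 0 called, also adjusted over the list alone). With e6 conidia, 18 probe sets were called, 10 higher and 8 lower. With quantile normalization they were 25 and 92. The count was 33 without mock replicate 2 and 45 without mock replicate 3. Ptx3, which encodes a secreted pentraxin that binds conidia, rose by 4.7 ± 0.94 (adjusted p = 0.0264) from a mock mean of 0.7. With the floor of 50 its difference was 0, and its call was lost under 9 of 14 alternatives. Pms2, a mismatch repair gene, fell by 2.29 ± 0.38 on the log2 scale (adjusted p = 0.0025) and did not pass with that floor (-0.33). Tnf differed by 0.01 ± 0.41 (adjusted p = 0.999).

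Whether the number of conidia mattered was asked by comparing e7 with e6 over both times. In WT, e7 gave higher Fosb, an AP-1 transcription factor (2.55 ± 0.42, adjusted p = 0.00077), Cxcl1 (1.98 ± 0.36, adjusted p = 0.00124) and Egr1 (1.66 ± 0.35, adjusted p = 0.00287). Gsr, which encodes glutathione reductase, was higher by 0.86 ± 0.17 (adjusted p = 0.00206), and Ncf4 was lower (-0.76 ± 0.16, adjusted p = 0.00265). In KO, e7 gave higher Cxcl1 (1.98 ± 0.41, adjusted p = 0.0139) and Tnf (1.21 ± 0.29, adjusted p = 0.0276), and lower Lat (-1.68 ± 0.25, adjusted p = 0.00204). Ctsb, which encodes the lysosomal protease cathepsin B, was lower in KO by -0.4 ± 0.08 (adjusted p = 0.0144), but at -0.12 it did not pass with quantile normalization. These dose effects rested on 8 arrays per dose in WT and 6 in KO. The WT comparison called 2443 probe sets, 1018 higher and 1425 lower, and 2 in a fit of only its groups, of which Cxcl1 passed in each of the 28 alternatives run. Gsr and Ncf4 lost their calls without 4 h e7 replicates 2 and 3. WT counts were 121 without 4 h e7 replicates 2 and 3, 1372 without 2 h e6 replicate 2, 1524 without 4 h e6 replicate 3, and 1356, 1270 and 4230 without 4 h e7 replicates 2, 3 and 4. The KO comparison called 324, 151 higher and 173 lower, and 1 in a fit of only its groups, which ended the calls of Tnf, Cxcl1, Lat and Ctsb. Of 21 alternatives Tnf was lost under 8, the others being without 2 h e6 replicates 1 or 3, 2 h e7 replicate 1, 4 h e6 replicates 1 or 3, or 4 h e7 replicates 1 or 3, and Cxcl1 under 2, the other being without 2 h e6 replicate 3. KO counts were 43 without 2 h e6 replicate 3, 70 and 143 without 2 h e7 replicates 1 and 2, 100 and 208 without 4 h e6 replicates 1 and 2, and 128, 190 and 110 without 4 h e7 replicates 1, 2 and 3. Immediate-early factors were higher in WT with 6 higher and 1 lower of 24 (the same adjusted over the list alone; camera adjusted p = 0.0463, adjusted p = 0.875 with an estimated correlation). In KO camera called them upward too (adjusted p = 0.000433, adjusted p = 0.393 with an estimated correlation; 0 called, 4 adjusted over the list alone). The lysosome list had 1 higher and 2 lower of 20 in KO (1 and 7 adjusted over the list alone; camera downward, adjusted p = 0.000433, adjusted p = 0.393 with an estimated correlation), and its median of -0.2 turned to 0.02 with quantile normalization.

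How the answer to e7 conidia developed was asked by comparing the difference from mock at 4 h with that at 2 h. In WT it was larger at 4 h for Maff (1.61 ± 0.29, adjusted p = 0.00323), for Tnf (1.84 ± 0.5, adjusted p = 0.038) and for Mt2, which encodes a metal-binding antioxidant protein (2.07 ± 0.51, adjusted p = 0.0237). It was lower at 4 h for Siglecf (-0.7 ± 0.18, adjusted p = 0.0267), which differed from mock by 0.03 at 2 h and -0.67 at 4 h. It was also lower for Tank, a regulator of NF-kB signalling (-1.27 ± 0.32, adjusted p = 0.025), which rose by 0.94 at 2 h (adjusted p = 0.0234) and differed by -0.33 at 4 h (adjusted p = 0.373). The 2 h call of Tank was lost in 7 of 18 alternatives, which were a fit of only these groups, the 3'/5' covariate and leaving out e7 replicates 1, 3 or 4 or mock replicates 2 or 3, and 3 of 4 conidia arrays lay above all mock arrays. In the time comparison the calls of Siglecf, Tank, Tnf and Mt2 were lost in 7, 9, 9 and 6 of the 28 alternatives run, and that of Maff in 1. Arrays whose removal ended the call were 2 h e7 replicates 2 and 3, 2 h mock replicates 2 and 4, 4 h e7 replicate 1 and 4 h mock replicates 1, 2 and 4 for Tnf, and 2 h e7 replicate 4, 2 h mock replicate 2, 4 h e7 replicate 2 and 4 h mock replicate 4 for Mt2. The difference in Cxcl2 did not pass (-0.16 ± 0.97, adjusted p = 0.96), and was 1.26 without 4 h mock replicate 3 (adjusted p = 0.265). WT called 617 probe sets, 241 higher and 376 lower, and 0 in a fit of only its groups. That count was 80 without both 4 h e7 replicates 2 and 3, 169, 268 and 2408 without 4 h e7 replicates 2, 3 and 4, between 255 and 404 without any of the 2 h mock arrays, between 318 and 371 without 2 h e7 replicate 1, 3 or 4, and between 324 and 405 without 4 h mock replicate 2, 3 or 4. Antioxidant targets had 1 higher of 20 (3 adjusted over the list alone; camera adjusted p = 0.0105, adjusted p = 0.0983 with an estimated correlation).

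In KO the time comparison called 384 probe sets, 71 higher and 313 lower, where quantile normalization gave 170 and 126 and the median over all genes moved by -0.2 on the log2 scale. Mob2, which encodes a kinase regulator, was higher at 4 h (3.16 ± 0.68, adjusted p = 0.0119), and Cd4, a T cell marker, was lower (-5.75 ± 1.41, adjusted p = 0.0288). With signals under 50 set to 50 the differences shrank to 1.46 and -1.41. The call of Mob2 was lost in a fit of only these groups. That of Cd4 was lost in 10 of 20 alternatives, which were that fit, the 3'/5' covariate, and leaving out 2 h e7 replicate 1 or 3, 4 h e7 replicate 2 or 3, 2 h mock replicate 1 or 2, or 4 h mock replicate 1 or 3. The change in Cxcl1 did not pass (0.84 ± 0.82, adjusted p = 0.643). KO counts were 641, 94 and 144 without 4 h e7 replicates 1, 2 and 3, 222 and 155 without 2 h e7 replicates 1 and 3, 233 without 2 h mock replicate 1, and 222 and 113 without 4 h mock replicates 1 and 3.

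The central question, whether KO macrophages respond differently from WT, was tested as the difference between the genotypes in each response. At 2 h with e7 conidia, Rgs1 rose less in KO (-2.25 ± 0.47, adjusted p = 0.0105), and this passed under each of the 24 alternatives run. Casp1 (-0.87 ± 0.17, adjusted p = 0.00625) and Lat (-2.69 ± 0.48, adjusted p = 0.00283) also differed, the first not in a fit of only these groups and the second not with the floor of 50. Cxcl2, called in WT and not in KO, was not shown to differ (-2.3 ± 1.05, adjusted p = 0.269), nor were Ccl3 (-2.54 ± 0.96, adjusted p = 0.174; both passed in a fit of only these groups), Cxcl1 (-0.7 ± 0.77, adjusted p = 0.71) and Egr1 (-0.56 ± 0.75, adjusted p = 0.769). This difference called 327 probe sets, 268 higher and 59 lower, and with quantile normalization 81 and 95, as the median over all genes moved by 0.22 on the log2 scale. Counts were 208, 195 and 194 without WT e7 replicate 1 and mock replicates 2 and 3, and 126, 134 and 170 without KO e7 replicates 1 and 3 and mock replicate 3. Heat shock genes lay lower (camera adjusted p = 0.00198, adjusted p = 0.739 with an estimated correlation; 0 called, 1 lower adjusted over the list alone). With e6 conidia at 2 h limma called 0 (929 at an unadjusted p under 0.05), with Cxcl2 at -1.65 ± 1.05 and Tnf at -0.19 ± 0.54 (adjusted p = 1 for both).

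At 4 h with e7 conidia, Klhl21, a substrate adaptor of a ubiquitin ligase, rose less in KO than in WT (-2.45 ± 0.41, adjusted p = 0.00829), as did Procr, the endothelial protein C receptor gene (-1.86 ± 0.33, adjusted p = 0.0098). Hyou1, an endoplasmic reticulum chaperone gene, differed by -2.09 ± 0.45 (adjusted p = 0.0451). Hyou1 lost its call in 14 of 25 alternatives, among them those without any WT mock array, without WT or KO e7 replicates 2 or 3, and without KO mock replicates 1 or 3, and Klhl21 and Procr lost theirs in 2, among them that without WT e7 replicates 2 and 3. The differences for Cxcl1 (-1.45 ± 0.77, adjusted p = 0.335), Tnf (-1.33 ± 0.54, adjusted p = 0.188), Cxcl2 (-1.78 ± 1.05, adjusted p = 0.391) and Hmox1 (-1.34 ± 0.47, adjusted p = 0.131) did not pass, though that for Cxcl2 did at -3.2 without WT mock replicate 3 (adjusted p = 0.0329). The 43 calls, 22 higher and 21 lower, became 0 in a fit of only these groups. They became 1 without both WT e7 replicates 2 and 3, 2389 and 220 without WT e7 replicates 4 and 1, 5 and 6 without WT e7 replicates 2 and 3, between 6 and 11 without any WT mock array, 28, 7 and 6 without KO e7 replicates 1, 2 and 3, and 14, 14 and 5 without KO mock replicates 1, 2 and 3. Antioxidant targets lay lower (camera adjusted p = 0.0113, adjusted p = 0.205 with an estimated correlation) and cell cycle genes higher (camera adjusted p = 0.000468, adjusted p = 0.666 with an estimated correlation), each with 0 called, and 0 and 6 adjusted over the list alone. With e6 conidia at 4 h 1 probe set was called, which has no symbol in the annotation and was chosen after its values were seen (3.98 ± 0.71, adjusted p = 0.0464), and 1370 reached an unadjusted p under 0.05. It was 0 without WT e6 replicates 2, 3 or 4, WT mock replicates 1, 2 or 4, KO e6 replicate 1 or KO mock replicate 1, and 3, 4 and 10 without KO e6 replicates 2 and 3 and KO mock replicate 3. Tnf, called in WT with e6 conidia and not in KO, was not shown to differ (-2.33 ± 0.54, adjusted p = 0.208), except with the floor of 50 (adjusted p = 0.0124).

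**Figure D3:**
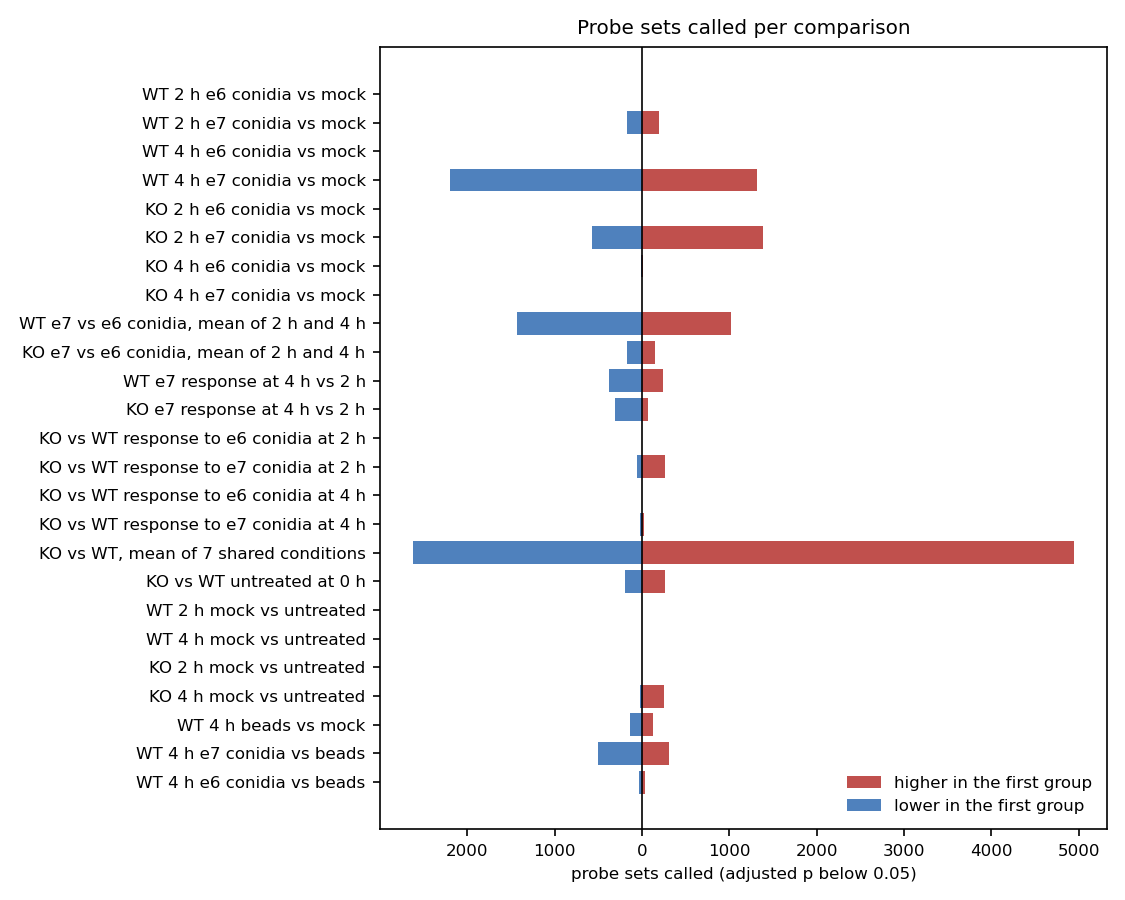
Number of probe sets called higher and lower (horizontal bars from 0) in each comparison. KO against WT over 7 conditions had 4945 higher and 2617 lower, and WT with e7 conidia at 4 h had 1321 and 2191.

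Apart from any response, KO macrophages were compared with WT. As a mean over the 7 shared conditions (21 KO and 28 WT arrays), Fstl1, which encodes a secreted glycoprotein, was higher in KO by 8.24 ± 0.21 on the log2 scale (adjusted p = 7.2e-28), and by 6.79 with signals under 50 set to 50, since its WT signals lie near the low end. Mfge8, which encodes a bridge between phagocytes and dying cells, was higher by 4.53 ± 0.1 (adjusted p = 9.21e-31), and Il7r, the interleukin 7 receptor gene, by 4.18 ± 0.18 (adjusted p = 6.38e-21). Mmp12, the macrophage elastase gene, was higher by 3.58 ± 0.19 (adjusted p = 1.31e-17), and Arg1, the arginase gene of alternatively activated macrophages, by 3.64 ± 0.61 (adjusted p = 1.37e-05). Ccl22 (1.74 ± 0.11), the cathepsin genes Ctsk (0.95 ± 0.06) and Ctsl (0.77 ± 0.04), the lipid carrier gene Fabp4 (1.28 ± 0.08) and Hmox1 (1.0 ± 0.12) were higher too. Lower in KO were Tgfb2, a growth factor gene (-1.46 ± 0.13, adjusted p = 1.16e-11), Fcgr1, an antibody receptor gene (-0.63 ± 0.06), and Tlr4 (-0.35 ± 0.07). Other subunits of the oxidase were slightly higher, Ncf1 by 0.4 ± 0.1, Ncf4 by 0.51 ± 0.09 and Cyba by 0.43 ± 0.1. Tnf (0.12 ± 0.14, adjusted p = 0.546) and Cxcl2 (0.5 ± 0.28, adjusted p = 0.17) did not pass the threshold, though Cxcl2 did in 2 of 61 alternatives, at 0.75 without the 3 WT 4 h arrays with high neutrophil markers (adjusted p = 0.000576) and without WT 4 h mock replicate 3 alone. The genes called here passed in each of the 61 alternatives run, and Arg1 in each of the 60 run for it, with a difference of 1.52 under the floor of 50. Clec7a, which encodes the fungal receptor Dectin-1, was higher by 0.17 ± 0.05 (adjusted p = 0.00984) and lost its call with the replicate block.

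The comparison over the 7 shared conditions called 7562 probe sets, 4945 higher and 2617 lower in KO, from 4336 genes. With quantile normalization 2848 were higher and 3721 lower, the median over all genes moving by 0.12 on the log2 scale, and 1360 calls, 18% of them, had both means under 50. Lysosome and phagosome genes had 15 higher of 20 (17 adjusted over the list alone), and their camera call held with an estimated correlation (adjusted p = 9.24e-08 and adjusted p = 0.0347). Camera also called the next lists at the preset correlation, each lost with an estimated correlation. Chemokines had 12 higher of 25 (12 adjusted over the list alone; adjusted p = 0.0506 with an estimated correlation), and cholesterol synthesis 13 higher and 1 lower of 18 (the same adjusted over the list alone; adjusted p = 0.0541 with an estimated correlation). Cell cycle genes had 16 lower of 29 (1 higher and 18 lower adjusted over the list alone; adjusted p = 0.232 with an estimated correlation), and cytokines 8 higher and 1 lower of 21 (9 and 1 adjusted over the list alone; adjusted p = 0.172 with an estimated correlation). The NF-kB pathway had 10 higher and 1 lower of 21 (the same adjusted over the list alone; adjusted p = 0.249 with an estimated correlation), and interferon-responsive genes 13 higher of 25 (13 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). Heat shock genes had 10 higher of 19 (11 adjusted over the list alone; adjusted p = 0.231 with an estimated correlation), and antimicrobial effectors 8 higher of 17 (8 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation). T and NK cell markers had 10 higher and 1 lower of 17 (the same adjusted over the list alone; adjusted p = 0.0541 with an estimated correlation), and B cell markers 5 higher of 10 (6 adjusted over the list alone; adjusted p = 0.152 with an estimated correlation). Monocyte and dendritic cell markers had 5 higher of 15 (5 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), and endothelium and stroma markers 8 higher of 14 (8 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation). Quantile normalization lowered many of these counts, to 8 higher for chemokines, 5 higher and 1 lower for cytokines, 9 and 2 for the NF-kB pathway, 9 higher for interferon-responsive genes and 8 for heat shock genes. It gave 6 higher and 1 lower for antimicrobial effectors, for T and NK cell markers and for endothelium and stroma, 3 higher for B cell markers, 5 and 1 for monocyte and dendritic cell markers, and 14 higher for lysosome genes, with 18 lower for cell cycle genes.

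The other 13 lists were not called by camera in this comparison. Fungal recognition genes had 11 higher and 4 lower of 29 (12 and 4 adjusted over the list alone), and antioxidant targets 10 higher of 20 (11 higher and 2 lower adjusted over the list alone). Proteases and matrix genes had 7 higher and 3 lower of 19 (8 and 4 adjusted over the list alone). The remaining counts were the same when adjusted over the list alone, except for lung epithelium and sex-linked genes. The NADPH oxidase had 4 higher and 1 lower of 10, immediate-early factors 5 and 6 of 24, glycolysis 5 and 4 of 19, and apoptosis regulators 5 and 6 of 20. Alternative activation had 5 higher and 1 lower of 14, alveolar macrophage markers 5 and 2 of 15, neutrophil markers 2 and 2 of 19, and erythroid markers 0 and 0 of 7. Lung epithelium markers had 2 higher and 2 lower of 20 (1 and 2 adjusted over the list alone), and sex-linked genes 0 and 1 of 4 (0 and 0 adjusted over the list alone). With quantile normalization alternative activation had 3 higher and 1 lower, its median going from 0.37 to 0.01, glycolysis 3 and 4, apoptosis regulators 5 and 4, proteases and matrix 6 and 4, fungal recognition 12 and 4, neutrophil markers 2 and 3 and lung epithelium 1 and 2, and the other counts stayed. For immediate-early, apoptosis, neutrophil and sex-linked genes the median and mean lay above 0 while camera leaned downward, and for the NADPH oxidase, lung epithelium and erythroid lists the median and mean differed in sign.

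In untreated mice the same contrast asked which of these differences preceded any instillation. Fstl1 was higher in KO by 8.09 ± 0.56 (12.25 ± 0.59 against 4.16 ± 0.39; SD, n = 3 and n = 4; adjusted p = 8.79e-13; 6.6 with the floor of 50) and Il7r by 4.06 ± 0.47 (adjusted p = 3.36e-07). Ccl3 was higher by 3.76 ± 0.68 (adjusted p = 0.00091), Clec4e by 2.2 ± 0.43 (adjusted p = 0.00241) and Fabp4 by 1.76 ± 0.21 (adjusted p = 6.09e-07). The enzymes of cholesterol synthesis Sqle (0.73 ± 0.14), Idi1 (0.8 ± 0.18) and Fdft1 (0.86 ± 0.21) were higher, and Tgfb2 was lower (-2.59 ± 0.34, adjusted p = 3.31e-06). On each of the 3 KO arrays these genes lay beyond the 4 WT arrays. Cxcl2 lay higher by 2.27 ± 0.74 without passing (adjusted p = 0.108), and passed in 2 of 16 alternatives.

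In untreated KO against WT, 450 probe sets were called, 260 higher and 190 lower, from 296 genes, and 58 in a fit of only the 7 arrays, in which Fstl1, Il7r and Cybb passed. Idi1 and Fdft1 lost their calls without KO replicates 1 or 2, and Fdft1 without WT replicate 3. The count was 114, 183 and 835 without KO replicates 1, 2 and 3, and 264 and 290 without WT replicates 3 and 4. Lists that camera called and that held with an estimated correlation were cholesterol synthesis (6 higher of 18, 10 adjusted over the list alone; adjusted p = 0.00043 with an estimated correlation) and antioxidant targets (3 higher of 20, 6 adjusted over the list alone; adjusted p = 0.0301 with an estimated correlation). Chemokines (4 higher of 25, 6 adjusted over the list alone), lysosome genes (3 higher of 20, 3 adjusted over the list alone) and T and NK cell markers (1 higher of 17, 2 adjusted over the list alone) held as well (adjusted p = 0.0467 with an estimated correlation for each).

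Mock instillation was compared with untreated mice to see what the procedure alone did. In WT, Cxcl2 did not pass at 2 h (0.77 ± 0.69, adjusted p = 0.761) or at 4 h (2.4 ± 0.69, adjusted p = 0.282), where it was 0.97 without mock replicate 3 (adjusted p = 0.8). Septin8, which encodes a cytoskeletal GTPase, fell at 4 h by 0.92 ± 0.17 on the log2 scale (adjusted p = 0.0343), a call lost in 9 of 18 alternatives. The other calls in WT, chosen after their values were seen, were a probe set of the Wnt effector gene Tcf7l2 (2.52 ± 0.43 at 2 h and 2.42 ± 0.43 at 4 h) and another of Klf9, a glucocorticoid-induced transcription factor gene (-1.42 ± 0.26 at 4 h). In KO, Wasl, which encodes the actin regulator N-WASP, fell at 4 h by 1.19 ± 0.22 (adjusted p = 0.00287; beyond the untreated arrays on 3 of 3), and Bcl6b, a transcriptional repressor gene near the low end of the signals, rose at 2 h by 3.39 ± 0.58 (adjusted p = 0.0193). With signals under 50 set to 50 the difference of Bcl6b was 0 and its call was lost. The procedure called 1 probe set in WT at 2 h, 3 in WT at 4 h and 1 in KO at 2 h, with 2238, 1797 and 1750 at an unadjusted p under 0.05 in limma. WT counts at 2 h were 15 without mock replicate 4 and 0 without any other array. At 4 h in WT they were 35 without mock replicate 4, 6 without untreated replicate 3, and 0 without mock replicates 1, 2 or 3 or untreated replicates 1 or 2. At 2 h in KO they were 11, 3 and 2 without mock replicates 1, 2 and 3 and 0 without untreated replicate 2. KO mock at 4 h called 271 probe sets, 248 higher and 23 lower, and 83 and 62 with quantile normalization, the median over all genes moving by 0.14. That count was 1 in a fit of only its 6 arrays, 97 and 124 without mock replicates 1 and 3, and 132 and 134 without untreated replicates 1 and 2. In WT at 4 h the cholesterol list lay higher (camera adjusted p = 3.87e-05, adjusted p = 0.0268 with an estimated correlation; 0 called, 3 adjusted over the list alone), as did neutrophil markers (camera adjusted p = 7.71e-05, adjusted p = 0.195 with an estimated correlation; 0 called, also adjusted over the list alone). The latter rests largely on mock replicate 3, at 8.7 where the other mock arrays lay between 4.94 and 5.44 and untreated arrays between 4.75 and 5.12.

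Beads, given at 4 h in WT on 2 arrays, asked how much of the answer any particle gives. Beads lowered Ccl22, a chemokine that attracts T cells (-1.52 ± 0.34, adjusted p = 0.0251), and raised Nfe2l2 (0.63 ± 0.14, adjusted p = 0.0246) and Cflar, an apoptosis inhibitor gene (0.97 ± 0.23, adjusted p = 0.0288), on both arrays beyond the 4 mock arrays. Cxcl1 rose by 2.44 ± 0.62 (adjusted p = 0.0413), with 1 of 2 arrays above all mock arrays. Against beads, e7 conidia gave higher Egr1 (2.31 ± 0.6, adjusted p = 0.0275), Gadd45b, a stress-response gene (1.94 ± 0.4, adjusted p = 0.00669), and Tnf (1.61 ± 0.43, adjusted p = 0.0318), and lower Siglecf (-0.72 ± 0.15, adjusted p = 0.00733). The difference in Cxcl1 did not pass (2.03 ± 0.62, adjusted p = 0.0547), but did in 7 of 17 alternatives. Against beads, e6 conidia gave higher Ccl22 (1.91 ± 0.34, adjusted p = 0.0153) and Mif, a cytokine gene (1.04 ± 0.24, adjusted p = 0.0452). With the 3'/5' covariate, on which the bead arrays lay apart from mock, the calls against mock were lost for Ccl22 (-1.35), Nfe2l2 (0.61), Cflar (0.63) and Cxcl1 (1.96). Those against beads were lost for Tnf with e7 conidia (1.4) and for Ccl22 (1.78) and Mif (0.7) with e6 conidia, while Egr1, Gadd45b and Siglecf passed and Cxcl1 with e7 conidia came to pass (2.41).

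Beads against mock called 257 probe sets, 125 higher and 132 lower (158 and 317 with quantile normalization), e7 conidia against beads 812, 309 higher and 503 lower (431 and 315), and e6 conidia against beads 74, 37 each way (135 and 47). The median over all genes moved by 0.13, -0.2 and -0.13 on the log2 scale between the scalings. Each of the 3 comparisons called 0 in a fit of only its groups. Of 17 alternatives the calls against mock were lost in 4 for Ccl22, 5 for Nfe2l2, 6 for Cflar and 7 for Cxcl1, and those of e7 conidia against beads in 6 for Egr1, 3 for Gadd45b, 6 for Tnf and 2 for Siglecf. With e6 conidia Ccl22 was lost in 3 and Mif in 8 of 16. With the 3'/5' covariate limma called 0 for beads against mock (2179 at an unadjusted p under 0.05), 2059 for e7 conidia against beads and 0 for e6 conidia against beads (2160 at an unadjusted p under 0.05). The bead arrays decided much of these counts: against mock they were 5 and 538 without bead replicates 1 and 2, for e7 conidia 81 and 469, and for e6 conidia 6 and 421. They were also 55, 41, 113 and 474 against mock without mock replicates 1, 2, 3 and 4, 245, 389 and 2772 without e7 replicates 2, 3 and 4, and 12, 16, 3 and 519 without e6 replicates 1, 2, 3 and 4. Where 1 bead array was left, it was assumed to vary like the other groups. Glycolysis and hypoxia genes lay higher with e7 conidia than with beads (2 of 19, 3 adjusted over the list alone; camera adjusted p = 0.000668, adjusted p = 0.0149 with an estimated correlation). So did immediate-early factors (4 of 24, 5 adjusted over the list alone; camera adjusted p = 0.000215, adjusted p = 0.293 with an estimated correlation). Alveolar macrophage markers lay lower with beads than mock (1 of 15, 6 adjusted over the list alone; camera adjusted p = 0.000481, adjusted p = 0.104 with an estimated correlation).

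**Figure D4:**
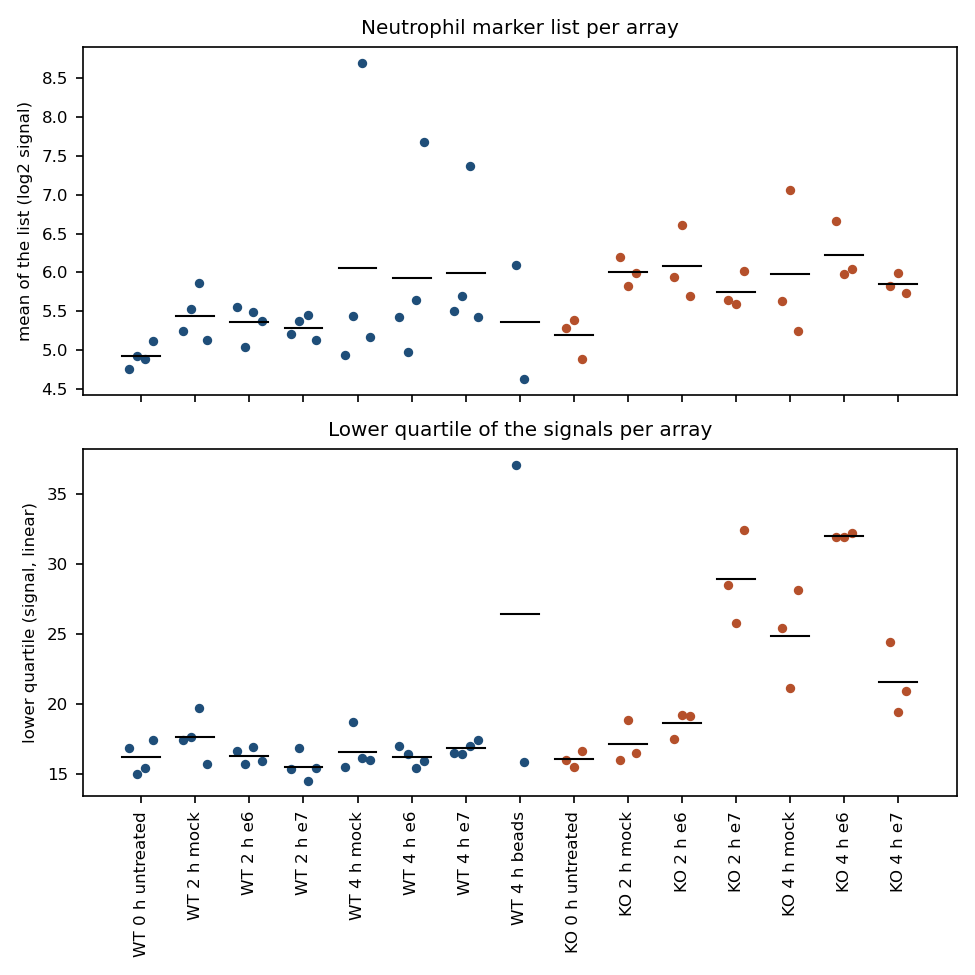
Mean log2 signal of the neutrophil markers (upper panel) and lower quartile of the signals (lower panel) on every array by group, with a point per array. WT 4 h mock replicate 3 lies at 8.7 for neutrophil markers, and the lower quartile averages 28.9 in KO with e7 conidia at 2 h.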

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

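The tests of explanations in this part were chosen only after the results they address had been seen. The counts over other splits of the arrays were planned. Those for differences between responses were rerun with the mean response taken out after the first counts had been seen, and both are given. The low end was first tested by the share of rises after quantile normalization, which evens out the distributions by its construction and so supports nothing. It was replaced by a floor of 50, and the share among brighter probe sets was added after its value in KO at 2 h was known. Tests of neutrophils were reworked to need all 19 markers, with 14 known to be higher.

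Single arrays lay far from the rest of their group in 22 of 217 values tested, where chance gives about 1 in 20, or 10.9. Only WT groups of 4 arrays were tested, and KO and bead arrays were not. KO 4 h mock replicate 2 had neutrophil markers at 7.06 against 5.25 and 5.63. KO 2 h e6 replicate 3 had Cybb at 6.77 against 8.32 and 8.89. WT 4 h mock replicate 3 stood out for neutrophil markers (8.7 against 4.94 to 5.44 on the other 3 arrays, as mean log2 signal), antimicrobial effectors (9.16 against 6.71 to 7.01), interferon-responsive genes (7.53 against 6.33 to 6.5) and fungal recognition genes (10.31 against 9.6 to 9.68). WT 4 h e7 replicate 3 stood out for neutrophil markers (7.37 against 5.42 to 5.69), fungal recognition genes (10.04 against 9.69 to 9.74) and T and NK cell markers (4.84 against 4.15 to 4.23). WT 4 h e6 replicate 4 did so for cytokines (6.56 against 5.65 to 5.77), interferon-responsive genes (7.25 against 6.36 to 6.47), fungal recognition genes (10.15 against 9.95 to 9.96), proteases and matrix genes (8.34 against 7.32 to 7.49) and the 3'/5' log2 ratio of the controls (4.75 against 1.29 to 1.81).

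The other distant arrays were WT 2 h mock replicate 4 for antioxidant targets (10.16 against 10.35), the 3'/5' ratio (0.93 against 1.41 to 1.47) and the poly-A spike-ins (8.05 against 8.61 to 8.72), WT 4 h e6 replicate 3 for lysosome genes (12.53 against 12.8 to 12.81), and WT 2 h e6 replicate 1 for cholesterol synthesis (9.86 against 9.69 to 9.71). WT 2 h e7 replicate 4 was distant for alternative activation (7.28 against 6.77 to 6.85) and replicate 1 for T and NK cell markers (3.49 against 4.35 to 4.42). WT 2 h mock replicate 2 was distant for B cell markers (5.44 against 4.88 to 4.9), mock replicate 3 for sex-linked genes (7.65 against 8 to 8.03) and WT 4 h e7 replicate 2 for erythroid markers (4.23 against 3.71 to 3.74).

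The WT 4 h mock array was weighed first. Neutrophils among the collected cells cannot be told apart from other causes. The array stood out by this list, so 14 of 19 markers above the other 3 arrays restate the pattern. Of the 50 genes in no list that follow these markers over the other arrays 39 were higher. The share of all genes in no list gives 9.55. Other cells or inflammation would raise such genes too. S100a8 (13.75 against 7.33 to 7.7), S100a9 (12.91 against 2.46 to 4.27) and Lcn2 (10.2 against 0.27 to 1.88) lay far above. Not higher were Fpr2, high on all mock arrays, and Elane, Mpo, Prtn3 and Stfa3, at 5.33 or less on all. Of the 19 markers, 6 had a mean signal of at least 50 in untreated WT and 5 are in another list. A wrong label was tested for e7 conidia alone and cannot be told apart. Over the 218 genes called at 2 h the array's mean signed difference from the other mocks was 0.08, within the -0.17 to 0.21 of the other mock arrays and below the 0.33 to 0.58 of the e7 arrays. Over genes called at 4 h without the array in question, on a scale from the mock arrays at 0 to the e7 arrays at 1, it lay at 0.17, but e7 replicate 4 lay at 0.16, within the 0.03 to 0.25 of the other mocks, so this scale does not separate the groups. On replicate 3 Cxcl2 (13.86) and Egr1 (10.79) were within the range of the e7 arrays (13.29 to 13.87 and 10.44 to 11.84) and far above the other mocks (7.78 to 8.71 and 6.87 to 7.23), while Cxcl1 (8.6) and Tnf (8.14) lay between both groups. The treatment field that names conidia is the same for all 4 mock arrays. Monocyte and dendritic cell (11 of 15) and lung epithelium markers (11 of 20) were also higher. Other cells thus stay open, as does an untested inflammatory reaction to the instillation. Without this array WT e6 at 4 h had 33 calls, not 2.

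The second pattern is the excess of rises over falls in KO at 2 h with e7 conidia, 1382 against 575. A raised low end of the signals on those arrays cannot be told apart as the cause: the lower quartile of the signals averaged 28.9 on them and 17.1 on KO mock arrays, the median difference was 0.81 for probe sets with a mean under 50 and 0.09 for the others. Its tests do not decide the question. With signals under 50 set to 50 the excess stayed, 73.4% of calls being higher instead of 70.6%. This floor keeps signals lifted over 50 as rises and removes falls under 50, so it cannot speak against a raised low end. Calls of probe sets with a mean under 50 were 686 higher and 53 lower, and of the others 696 and 522, or 57.1% higher, so that an excess remained there too. A response shared with WT cannot be told apart as a cause of the excess. Genes called in both genotypes at 2 h were 21 higher and 23 lower, 47.7% higher against 68.9% of all genes called in KO, but with the 3'/5' covariate 3 higher and 0 lower were called in both, too few to give a direction. Why the low end was raised was not tested.

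The third pattern is the wide difference between KO and WT over 7 conditions. DNA of the targeting strain carried along around Cybb is unlikely to be the whole cause: of the 20 measured genes next to Cybb 4 were called, and 34.7% of X-linked genes were called against 35% of the others (Fisher's exact p = 0.915). A raised low end on KO arrays cannot be told apart as the cause of the excess of rises. With signals under 50 set to 50 the share of calls higher in KO was 61.1% instead of 65.4%, but this floor keeps signals lifted over 50 as rises. The share was 93.2% among probe sets with a mean under 50 and 49.5% among the others. A raised low end does not account for single genes such as Fstl1, which stayed at 6.79 or more on the log2 scale in each alternative run. The labels give no dates, so a batch that follows genotype cannot be told apart from the genotype, and the oxidase defect itself stays open as untested.

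Differences between groups in a response were tested directly. The answer to e7 conidia differed between 4 h and 2 h at 617 probe sets in WT and 384 in KO, and between KO and WT at 327 probe sets at 2 h and 43 at 4 h, and that to e6 conidia at 1 probe set at 4 h. Other splits of the same arrays show how far chance can be excluded. A split can turn the mean response itself into calls, so the mean response of each pair was taken out first. Chance can then be excluded for the time comparisons, 617 in WT against at most 405 (1 of 100 splits as large) and 384 in KO against at most 35 (1 of 100). It can be for e7 conidia in KO against WT as well, 327 at 2 h against at most 2 (1 of 100) and 43 at 4 h against at most 1202 (3 of 100). It cannot be for e6 conidia, 1 at 4 h against at most 11 (33 of 100) and 0 at 2 h against at most 1 (100 of 100). With the mean response kept, as first run, the splits as large were 4 of 100 for time in WT (at most 1678), 3 in KO (at most 654), 5 for KO against WT with e7 conidia at 2 h (at most 2444) and 5 at 4 h (at most 1417), and 50 and 100 with e6 conidia at 4 h and 2 h (at most 19 and 2). The exclusions for KO against WT with e7 conidia, at 2 h and at 4 h, thus both depend on this step.

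For conidia against mock in WT, chance can be excluded for e7 conidia at 2 h (365 against at most 2 in other splits, 1 of 35 as large) and at 4 h (3512 against at most 3248, 1 of 35). At 4 h the 4 other splits with the most calls, this highest among them, exchange e7 replicate 4 for 1 of the 4 mock arrays. The count rests mainly on e7 replicates 2 and 3 (204 without both). Chance cannot be excluded for e6 conidia, with 0 at 2 h against at most 31 (35 of 35) and 2 at 4 h against at most 116 (6 of 35), where the highest count came from exchanging e6 replicate 4 for mock replicate 3, arrays that lay apart above. By the share of drawn splits alone chance can be excluded for dose, 2443 in WT against at most 2628 (3 of 100) and 324 in KO against at most 1641 (2 of 100). The highest in KO exchanges all 4 h arrays, and so measures a difference between the times in the effect of dose. It can be as well for KO against WT over 7 conditions, 7562 against at most 11 (1 of 100), and in untreated mice, 450 against at most 99 (1 of 35). For mock against untreated in WT it cannot be at 2 h, 1 against at most 1 (5 of 35), and by the share of splits alone it can at 4 h, 3 against at most 1 (1 of 35). So few calls carry little weight, as the count was 0 with quantile normalization, with the 3'/5' covariate, in a fit of only these groups and without any of 5 single arrays. With 3 arrays against 3 the 10 splits are too few for a share under 0.05: the real counts and the highest others were 0 and 2 for KO with e6 conidia at 2 h (10 splits as large), 1957 and 1 with e7 at 2 h (1 split), 18 and 22 with e6 at 4 h (2 splits), 1 and 4 with e7 at 4 h (6 splits), 1 and 1 for KO mock at 2 h (3 splits), and 271 and 3 for KO mock at 4 h (1 split).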

How the results depend on the processing

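Among the settings here, the floor of 50 and the removal of WT arrays with high neutrophil markers or lying apart were chosen after seeing the data, and the others were planned. Of 100 gene results given as passing, 26 kept their call in each alternative run and 74 lost it in at least 1, and 0 values turned sign. The 26 include Cybb, Fstl1 and Il7r in both comparisons of KO with WT, Cxcl2 and Rgs1 in WT at 2 h with e7 conidia, and Rgs1 in the difference between the genotypes there. Counts of probe sets called are compared below with those reported, and those not given for a setting stayed within 1.5 times. The cause of a move was not tested except where stated.

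Without the dimmer part of the probe sets, by construction fewer tests, 8 of 25 counts stayed within that range. The rest were 929 in WT at 2 h with e7, 4 and 5 in KO at 4 h with e6 and e7, 637 in the KO dose comparison, and 1305 and 108 in the WT and KO time comparisons. KO against WT gave 107, 0 and 779 for the responses to e7 at 2 h, e6 at 4 h and e7 at 4 h, and 4616 over 7 conditions. Mock gave 0 and 27 in WT at 2 h and 4 h and 0 and 92 in KO, and beads 509 against mock, 1403 against e7 and 125 against e6.

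With 1 probe set per gene, also fewer tests, 12 counts stayed. KO conidia gave 1090 with e7 at 2 h, and 10 and 3 with e6 and e7 at 4 h. Dose in KO gave 205 and time in KO 163. KO against WT gave 153, 0 and 69 for the responses to e7 at 2 h, e6 at 4 h and e7 at 4 h, and 4445 over 7 conditions. WT mock gave 0 at 2 h and 1 at 4 h, KO mock at 4 h 117, and beads against e6 33.

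Fitting only the groups of a comparison leaves fewer arrays to estimate the spread, and 5 counts stayed. WT gave 4 with e7 at 2 h and 0 with e6 and 0 with e7 at 4 h, and KO 877 with e7 at 2 h and 0 with e6 and 0 with e7 at 4 h. Dose gave 2 in WT and 1 in KO, time 0 in WT and 225 in KO. KO against WT gave 4 and 0 for the responses to e6 and e7 at 4 h and 58 in untreated mice. Mock gave 1 in KO at 4 h, else 0, and beads 0 each.

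With a trend and robust moderation, 17 stayed. The others were 592 in WT at 2 h with e7, 9 and 3 in KO at 4 h with e6 and e7, 0 and 336 for the e6 and e7 responses at 4 h, 3 and 8 for WT mock at 2 h and 4 h, and 404 for beads against mock. Array quality weights left 7. They gave 1342 in WT at 2 h with e7 and 4 at 4 h with e6, and in KO 4672 at 2 h with e7, 53 at 4 h with e6 and 34 with e7. Dose in KO gave 936, and time 1282 in WT and 1629 in KO. KO against WT gave 1211, 2 and 968 for the responses to e7 at 2 h, e6 at 4 h and e7 at 4 h, and 2062 in untreated mice. Mock gave 243 and 98 in WT and 197 and 878 in KO at 2 h and 4 h, and beads 396 against e7 and 16 against e6.

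Replicate number as a block left 18, though no comparison had all its same-numbered pairs alike by over 0.1 in correlation, so the numbers do not pair the arrays. It gave 583 in WT at 2 h with e7, 4 at 4 h with e6, 522 for dose in KO, 0 and 68 for the e6 and e7 responses at 4 h, 515 for beads against mock and 1506 against e7. Of the 94 lists called by camera, 86 were called with the block.

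Quantile normalization left 14 counts, and 0 calls changed direction. It gave 117 and 7 in KO at 4 h with e6 and e7, 490 for dose in KO, 401 for time in WT, 176 and 7 for the responses to e7 at 2 h and e6 at 4 h, 0 and 0 for WT mock at 2 h and 4 h, 145 for KO mock at 4 h, 475 for beads against mock and 182 against e6. The 3'/5' covariate left 11. It gave 45 in WT at 2 h with e7, 7 in KO at 4 h with e6, 1616 and 742 for dose and 1426 and 212 for time in WT and KO, 0 and 5 for the e6 and e7 responses at 4 h, 0, 0 and 3 for mock in WT at 2 h and 4 h and in KO at 2 h, and 0, 2059 and 0 for beads against mock, e7 and e6.

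Signals under 50 set to 50 left 10 counts. The others were 612 in WT at 2 h with e7, 4 in KO at 2 h with e6, 1030 and 71 at 4 h with e6 and e7, 1127 for dose and 844 for time in KO, 511, 420 and 274 for the responses to e7 at 2 h, e6 at 4 h and e7 at 4 h, 0, 7 and 2 for mock in WT at 2 h and 4 h and in KO at 2 h, and 2635, 3235 and 2240 for beads against mock, e7 and e6.

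With WT 2 h mock as the reference, WT e6 at 4 h gave 41 and beads 921. Without WT 2 h e7 replicates 1 and 2, which had little poly-A spike-in signal, the counts were 56 in WT at 2 h with e7, 872 for dose in WT and 140 for the e7 response at 2 h. Without the 3 WT 4 h arrays with high neutrophil markers they were 95 and 1165 for e6 and e7 in WT at 4 h, 212 for time in WT, 0 and 12 for the e6 and e7 responses at 4 h, 0 for WT mock at 4 h, and 376 and 673 for e7 and e6 against beads. Without WT 4 h e7 replicates 2 and 3 they were 204 in WT at 4 h with e7, 121 for dose and 80 for time in WT, 1 for the e7 response at 4 h and 200 against beads.

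Leaving out 1 array at a time gave these ranges. In WT they were 0 to 1 and 63 to 591 at 2 h with e6 and e7, and 2 to 33 and 1622 to 5305 at 4 h. In KO they were 0 to 2 and 688 to 1274 at 2 h, and 13 to 45 and 1 to 13 at 4 h. Dose gave 1270 to 4230 in WT and 43 to 369 in KO, time 169 to 2408 and 94 to 641. The differences between KO and WT in response gave 0 to 0 and 126 to 302 for e6 and e7 at 2 h, and 0 to 10 and 5 to 2389 at 4 h. KO against WT gave 7034 to 7879 over 7 conditions and 114 to 835 in untreated mice. Mock gave 0 to 15 and 0 to 35 in WT and 0 to 11 and 97 to 206 in KO at 2 h and 4 h, and beads 5 to 538 against mock, 81 to 2772 against e7 and 3 to 519 against e6.

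Signal over background limits these results most at low signals, as in the simulated data.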

Other observations

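No further hypothesis was tested here, and the values below were looked at only after the comparisons were seen. Over all 51 arrays the leading 3 principal components held 21.6%, 18.8% and 10.8% of the variance. Poly-A spike-in signal, as mean log2, lay between 2.19 and 7.45 on the WT 2 h e7 arrays and between 8.05 and 8.72 on the WT 2 h mock arrays. The lower quartile of the signals was 37.1 and 15.8 on the bead arrays, and its group mean was 32 in KO with e6 conidia at 4 h and 16 in untreated KO. Across genes, the log2 differences from mock with e7 conidia in WT and KO correlated at 0.01 at 2 h and 0.01 at 4 h, where genes are not independent replicates. Among genes called at 2 h, 21 were higher in both genotypes where chance gives 7.47. Another 23 were lower in both where chance gives 2.42, and 0 were opposite. With the 3'/5' covariate 3 higher and 0 lower were called in both. The low correlation over all genes therefore does not show that the responses were unrelated.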
